A study of Mus musculus with 6 samples.

How the data were processed

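RNA-seq of mouse OPC cultures was available as 6 count tables, for 3 control and 3 knockout libraries. Per the labels' protocols, stranded poly(A) libraries were sequenced in paired-end mode. The deposited counts are whole numbers of read pairs per gene symbol, not normalised, and the authors' steps are known only in part. The submitters' processing notes name HISAT2 2.2.1, HTSeq 0.12.4, DESeq2 1.26.0 and the mm10 genome build without saying what each was used for. Their parameters, the gene annotation and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, values of overlapping genes are uncertain, as are those of genes with near-identical copies.

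Each table ended in 5 summary entries that name no gene, which were left out of library sizes and tests. Their shares of read pairs were, as mean over control and over knockout libraries, 19.7% and 20.8% for pairs in no gene, 1.46% and 1.45% for ambiguous pairs, 3.11% and 3.83% for pairs of low alignment quality, 1.03% and 1.25% for unaligned pairs, and 3.46% and 3.41% for pairs with several alignments. Gene counts summed to between 26015604 and 28114968 per library. Of 24421 genes listed, 20148 had a count in some library and 15906 passed edgeR's expression filter, holding 99.95% of gene counts. The number of per-sample columns not used was 0. GC content, length and coordinates came from the GENCODE annotation of GRCm38 (mm10), matched by symbol for 24026 listed and 15784 tested genes.

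Groups came from the labels' genotypes. The main test, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Counts were scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term, two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested. A gene was called at an adjusted p under 0.05. CPM values are normalised by TMM, and fold changes are knockout over control. Beside this test the same model was fitted with the replicate number as a block. The labels give both groups the numbers 1, 2 and 3 without saying what a number marks. Deviations of log2 CPM from the group mean correlated at 0.712, 0.682 and 0.654 between same-numbered libraries, so the numbers were taken to pair the libraries. They were negatively correlated between all others, which subtracting the group mean itself favours, so that adds no support. The common biological coefficient of variation was 0.315 without the block and 0.104 with it, at 4 and 2 residual degrees of freedom.

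Of 32 lists fixed beforehand, 30 had at least 5 tested genes. These covered the oligodendrocyte lineage, progenitor transcription factors, cell cycle, stress, translation, signalling, matrix and metabolism, ribosomal proteins, histones and the respiratory chain, and markers of 6 other cell types. The blood markers had fewer than 5 tested members and the mitochondrially encoded genes were not among the genes listed, so neither was tested. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, then with an estimated correlation and with fry. With an estimated correlation camera uses only the residual degrees of freedom, 2 with the block and 4 without. Few lists could then pass, and the smallest unadjusted camera p with the block was 0.0251. A call lost in that setting therefore does not show that correlation among genes had made it. Fry's directional test called 0 lists with or without the block, and its test for change in either direction called 0 without and 14 with it, 8 of them among the lists that camera called. A list of 65 liver genes was written after the values were seen.

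The rule for named genes took Prrc2b, Prrc2a, Prrc2c, Sox2 and Olig2 always. It took the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM and all libraries of one group on one side of the other, passing over predicted gene models, and up to 4 genes per list by smallest adjusted p, of which 1 is not reported here. As 0 genes met the part on size without the block, that part was applied to the blocked test, with the same direction in all 3 pairs in place of separated groups. There 238 rises and 342 falls met it, and 7 rising and 9 falling predicted models were passed over.

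Alternatives were DESeq2 size factors, library totals or upper quartile scaling, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0 and limma-voom as tests, other thresholds, and each library left out. Added after seeing the data were a correction for GC content, made by shifting each library's median in 20 GC bins, and all of these settings together with the block, where both libraries of a number were left out together. Both tests were tested on simulated data, in 3 sets of counts for 15906 genes with 200 changed genes each. Without the block 0%, 0.667%, 16.7% and 61.3% of genes changed 1.3-, 1.5-, 2- and 4-fold were recovered, and with it 36.0%, 61.3%, 80.7% and 92.7%. False calls made up 9.23% and 8.76% of calls. The simulation without the block drew each library independently around a single mean per gene. The real same-numbered libraries shared differences, so its recovery need not hold for the unblocked test of these data.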

Results

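Gene expression was measured by RNA-seq in 6 libraries of mouse oligodendrocyte progenitor cells (OPCs), the dividing cells that give rise to myelin-forming oligodendrocytes. A group of 3 libraries came from mice with floxed Prrc2b alleles and no Cre (control). The other 3 came from mice that also carried Olig2-Cre (knockout). It drives recombination in cells with Olig2 expression, which include but need not be limited to the oligodendrocyte lineage. Per the labels' protocols, cells were taken from the cortex of pups at postnatal day 4, panned on GalC and then O4 antibody, and cultured in a proliferation medium. The series' design text names brain tissue of the same age instead. The labels do not say whether replicates came from separate animals. Sex-linked transcripts, given at the end, show that the libraries of a group were not the same pool of cells divided. The number of animals per library is not known, so p-values measure only the spread between these libraries. The comparison asks which transcripts differ when Prrc2b, which encodes a member of the PRRC2 family of RNA-binding proteins, is targeted in this lineage. No library carried Olig2-Cre without floxed Prrc2b. Effects of the Cre or its allele therefore cannot be told apart from those of Prrc2b loss in any difference below. The same holds for a technical difference between the groups, which the replicate block does not remove. Shares of read pairs outside the gene counts did differ by group, as given under the results flagged for a closer look. The series' stated interest is how reduced myelin arises with Prrc2b deficiency, and myelin itself was not analysed here. Gene counts per library ranged from 26015604 to 28114968, and 15906 of 24421 listed genes were tested.

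The libraries carried transcripts of several cell types. The 26 OPC identity genes summed to 5081 ± 1160 CPM in control and 5374 ± 1653 in knockout libraries (SD, n = 3 each). The 28 neuronal markers summed to 6358 ± 1090 and 5725 ± 1192 CPM, and the 25 astrocyte markers to 4008 ± 1212 and 4535 ± 1315 CPM. Pdgfra, the growth factor receptor by which OPCs are usually recognised, stood at 303 ± 106 CPM in control and 321 ± 105 CPM in knockout libraries. Ttr, a choroid plexus transcript, stood at 761 ± 853 and 1351 ± 1059 CPM. Pdgfra was singled out after its values were seen.

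Prrc2b transcript was lower in every knockout library than in every control library. Its level was 990 ± 105 CPM in control and 744 ± 88.3 CPM in knockout libraries (SD, n = 3), and its counts were 25263, 29127 and 26164 against 17830, 23153 and 20055. The gene (ENSMUSG00000039262.16) lies on chromosome 2 from 32151082 to 32234537 of GRCm38, on the plus strand. Its log2 fold change was -0.41 (SE 0.13), with an unadjusted p of 0.0191 and an edgeR quasi-likelihood adjusted p of 1.00. With the replicate number as a block, Prrc2b fell by 0.41 (SE 0.06, edgeR adjusted p = 0.00688), to 0.750 of the control level, and over the alternatives and left-out pairs with the block that adjusted p was at most 0.0215. Which exons are floxed is not given in the sources used here, and a count over the whole gene does not separate reads of deleted exons from the rest.

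Sox2, a transcription factor of neural and oligodendrocyte progenitors, fell with the replicate block in all 3 same-numbered pairs. It went from 490 ± 118 to 402 ± 120 CPM (SD, n = 3), a blocked log2 fold change of -0.30 (SE 0.04, edgeR adjusted p = 0.00893). Without the block its log2 fold change was -0.29 (SE 0.25, edgeR adjusted p = 1.00). Across the alternatives and left-out pairs its blocked adjusted p was at most 0.0442. Sox2 lies within the span of the non-coding gene Sox2ot on the same strand, and how reads in shared exons were counted is not given in the sources used here. Olig2, the lineage transcription factor whose locus drives the Cre, was lower in all 3 pairs, at 235 ± 108 CPM in control and 184 ± 138 CPM in knockout libraries, but its blocked change of -0.50 (SE 0.12) did not pass (edgeR adjusted p = 0.0533). That adjusted p ranged from 0.00366 to 0.320 over alternative settings with all pairs, and was 0.000501, 0.0754 and 0.165 without the pairs numbered 1, 2 and 3. As only the knockout libraries carried Olig2-Cre, the Olig2 values cannot separate Prrc2b loss from an effect of the Cre allele. The paralogs of Prrc2b did not pass either in the edgeR test. Prrc2a stood at 1042 ± 188 and 942 ± 150 CPM (blocked log2 fold change -0.14, SE 0.05, edgeR adjusted p = 0.148, DESeq2 0.0154, limma-voom 0.0210, but 0.00 with adjusted p = 0.999 after GC correction), and Prrc2c at 587 ± 6.51 and 593 ± 26.7 CPM (0.01, SE 0.05, edgeR adjusted p = 0.915).

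**Figure D1:**
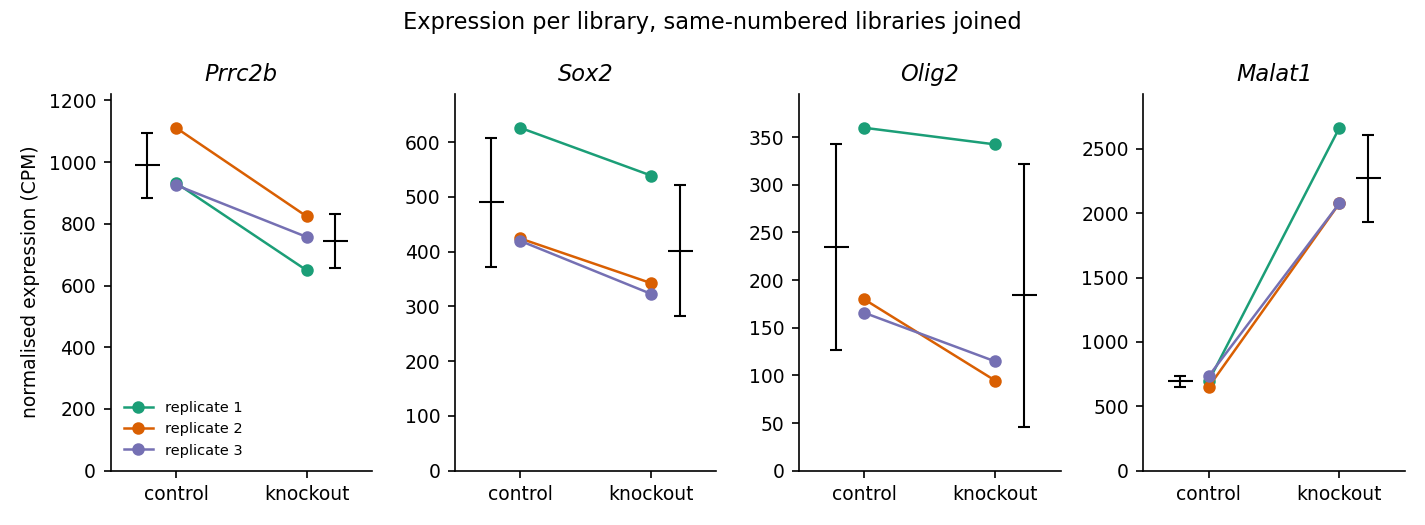
Normalised expression (CPM, linear axis from 0) of Prrc2b, Sox2, Olig2 and Malat1 in each library, with same-numbered control and knockout libraries joined by a line and the group mean ± SD (n = 3) in black beside the points. Prrc2b lies between 649 and 824 CPM in the knockout libraries and between 926 and 1111 CPM in the control libraries, and Malat1 lies between 2077 and 2665 CPM in the knockout libraries.

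Across all genes, edgeR and limma-voom called 0 genes without the block. The edgeR quasi-likelihood test called 0 of 15906 genes at an adjusted p under 0.05, with 274 genes at an unadjusted p under 0.05 where 795 would be expected by chance. DESeq2 called 20 genes without the block (10 higher and 10 lower, 14 of at least 2-fold). The smallest edgeR adjusted p was 0.113. With the replicate number as a block, edgeR called 604 genes, of which 250 rose and 354 fell in the knockout, with a median absolute log2 fold change of 0.37. Of these, 81 changed at least 2-fold, 73 of them upward and 8 downward. DESeq2 called 703 and limma-voom 712 genes with the block. The share of rises among calls was 41.4% and depended on scaling. With library totals alone 271 genes rose and 231 fell (54.0% rises), and with upper quartile scaling 289 rose and 247 fell (53.9% rises). Without the pair numbered 3, which leaves 4 libraries, the blocked count was 174 (62 rises and 112 falls, 33 of at least 2-fold), and without the pair numbered 1 it was 444 (276 rises and 168 falls, 131 of at least 2-fold). After correction for transcript GC content it was 371 (196 rises and 175 falls). In 6.34% of tested genes (1009) all knockout libraries lay on one side of all control libraries, against 10% if the libraries were exchangeable. As same-numbered libraries shared differences, 10% is not the share to expect here, and no conclusion is drawn from it.

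**Figure D2:**
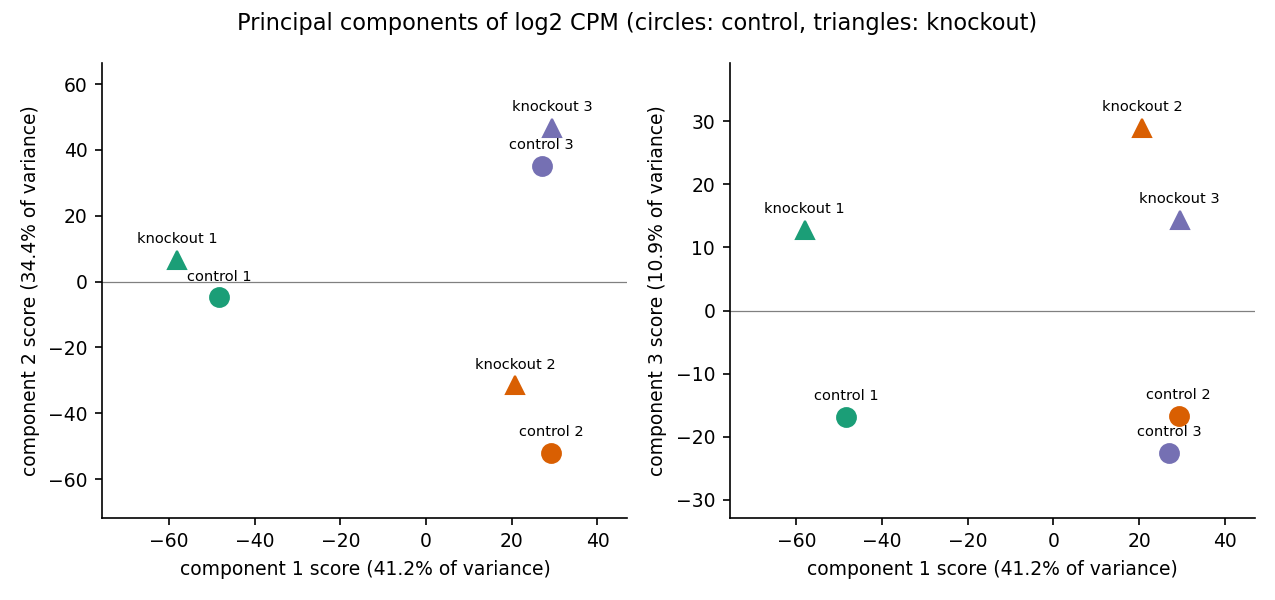
Scores of the 6 libraries on principal components of log2 CPM, with component 1 against component 2 on the left and component 1 against component 3 on the right, circles for control and triangles for knockout libraries, and a colour per replicate number. Components 1 and 2 (41.2% and 34.4% of the variance) place same-numbered libraries side by side, and component 3 (10.9%) has all control libraries below 0 and all knockout libraries above 0.

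Because 0 genes met the naming rule without the block, it was applied to the blocked test after the values were seen, among genes with a mean of at least 2 CPM that moved one way in all 3 pairs. The 10 largest rises included Malat1, the liver transcript Apoa4 and 3 endothelial markers. Malat1, an abundant nuclear non-coding RNA, rose from 694 ± 41.8 to 2273 ± 339 CPM (SD, n = 3), a blocked log2 fold change of 1.70 (SE 0.08, edgeR adjusted p = 3.4e-05). Without the block its edgeR adjusted p was 0.113. Apoa4, an apolipoprotein made in liver and intestine, rose by 2.29 on the log2 scale (SE 0.30, edgeR adjusted p = 0.00647). Rises of 2.16 in Ly6c1, 1.97 in Ly75, 1.88 in Pcdh12, 1.79 in Slc38a5, 1.75 in Ctla2a, 1.66 in Abcb1a, 1.64 in Cldn5 and 1.62 in She completed the 10 largest. Ly6c1, Abcb1a and Cldn5 belong to the endothelial markers fixed beforehand, Abcb1a being the drug efflux pump and Cldn5 the tight junction protein of the blood-brain barrier. Blocked edgeR adjusted p-values of these 8 genes were 0.00294 for Cldn5 and 0.0252 for Ly75, with the others between. Levels were low, from 0.743 CPM for Ly6c1 to 7.12 CPM for Cldn5 in control libraries. Without the pair numbered 3, all of these 8 genes except Cldn5 lost the call (edgeR adjusted p 0.0616 for Pcdh12 to 0.251 for Ly75).

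The 10 largest falls by the same rule included 4 liver transcripts. Saa1 fell by 3.25 on the log2 scale (SE 0.32, edgeR adjusted p = 0.00258), Serpina1e by 2.49 (SE 0.29), Mup3 by 1.93 (SE 0.25) and Serpina3k by 1.13 (SE 0.21). These genes encode secreted proteins of the liver, and each has near-identical copies in the genome among which counting may divide reads, so single-gene values are uncertain. Erdr1, which lies in the pseudoautosomal part of the sex chromosomes, fell by 1.91 (SE 0.30) and its reads can be shared between both. Gtf3a, a transcription factor of RNA polymerase III, fell by 0.83, Srp54a, a signal recognition particle subunit with near-identical copies, by 0.83, the chromatin factor Adnp by 0.82, Prr7 by 0.80 and Scand1 by 0.77. Blocked edgeR adjusted p-values of the 10 genes were 0.00258 for Saa1 and 0.0401 for Gtf3a, with the others between. Gtf3a, Srp54a, Adnp and Serpina3k lost the call without the pair numbered 3 (edgeR adjusted p 0.162, 0.160, 0.0591 and 0.122), Gtf3a and Srp54a also without the pair numbered 2 (0.102 and 0.0993), and Gtf3a and Serpina3k without the pair numbered 1 (0.106 and 0.0907). Gtf3a also lost it after GC correction (0.0582, at -0.81, SE 0.18 before and after), with library totals (0.0514) and with DESeq2 (0.0702), and Srp54a among genes with a mean of at least 5 CPM (0.0545).

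Among progenitor transcription factors and neuronal markers a larger share fell with the block than among all tested genes (354 of 15906). It was still fewer than 1 in 3 of each list, and 0 rose. Of 24 stem and progenitor transcription factors and related genes, 7 fell, 0 rose and 17 did not pass over all genes tested (10 fell and 3 rose adjusted over the list alone). Sox4 went from 802 ± 109 to 607 ± 90.5 CPM (log2 fold change -0.40, SE 0.04, edgeR adjusted p = 0.00294), Nfix from 873 ± 11.5 to 708 ± 42.1 CPM (-0.30, SE 0.05) and Sox11 from 868 ± 222 to 725 ± 193 CPM (-0.26, SE 0.04). Nfix and Sox11 lost the call without the pair numbered 1 (edgeR adjusted p 0.0765 and 0.0633), and Sox11 also without the pair numbered 2 (0.0537). Sox2 belongs to this list and the study is known to have taken it up, so its fall here is not independent evidence. As a set the list was lower (camera adjusted p = 0.00165), with adjusted p = 0.381 with an estimated correlation. Of 28 neuronal markers 7 fell, 0 rose and 21 did not pass (12 fell adjusted over the list alone), with a median of -0.15. Dlx2 and Dlx1, homeobox genes of inhibitory neuron precursors, changed by -0.44 (SE 0.04) and -0.24 (SE 0.04), Neurod2, of excitatory neurons, by -0.69 (SE 0.07), and Elavl3, a neuronal RNA-binding protein, by -0.28 (SE 0.04). The edgeR adjusted p was 0.00221 for Dlx2 and 0.0118 for Dlx1. Dlx1 lost the call without the pair numbered 3 (edgeR adjusted p = 0.0577). The set was lower (camera adjusted p = 1.72e-09), with adjusted p = 0.381 with an estimated correlation.

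Some markers of each of 4 other cell types rose with the block and 0 fell, the largest share among endothelial markers. Over all tested genes 250 of 15906 rose. Of 19 endothelial markers 12 rose, 0 fell and 7 did not pass (18 rose adjusted over the list alone), with a median log2 fold change of 1.26. Kdr, the main receptor for vascular endothelial growth factor, went from 14.2 ± 10.1 to 36.5 ± 27.9 CPM (SD, n = 3; blocked log2 fold change 1.37, SE 0.11, edgeR adjusted p = 0.00117). Flt1 rose by 1.56 (SE 0.16) and the vascular cadherin Cdh5 by 1.26 (SE 0.13). Of 13 ependymal and choroid plexus markers 6 rose and 7 did not pass (13 rose adjusted over the list alone), with Ttr at 1.16 (SE 0.16) and the cilium-associated genes Ccdc153 at 1.11 (SE 0.20) and Dynlrb2 at 1.01 (SE 0.19). The latter pair lost the call without the pair numbered 3 (edgeR adjusted p 0.0631 and 0.0695). Of 25 astrocyte markers 8 rose and 17 did not pass (16 rose adjusted over the list alone), among them Gfap (107 ± 55.1 to 153 ± 59.5 CPM, log2 fold change 0.55, SE 0.06), the gap junction protein gene Gja1 (0.32, SE 0.04) and the water channel gene Aqp4 (0.33, SE 0.05). Of 22 pericyte and fibroblast markers 4 rose and 18 did not pass (13 rose adjusted over the list alone). Vtn rose by 0.42 (SE 0.07) and Rgs5 by 0.49 (SE 0.08), and both lost the call without the pair numbered 3 (edgeR adjusted p 0.205 and 0.172). Camera adjusted p-values were 1.31e-44 for endothelial, 1.27e-17 for ependymal and choroid plexus, 1.23e-12 for astrocyte and 6.31e-12 for pericyte and fibroblast markers. For each of these lists adjusted p = 0.269 with an estimated correlation.

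Oligodendrocyte lineage genes mostly did not pass. Of 26 OPC identity genes 0 rose and 0 fell (0 adjusted over the list alone), with a median log2 fold change of 0.00. Apart from Olig2, the nearest to the threshold was Ptprz1, a receptor phosphatase of OPCs, at 0.18 (SE 0.06, edgeR adjusted p = 0.123), and it passed with DESeq2 (0.00663), limma-voom (0.0168) and no filter (0.0358) but in no other setting. Of 19 genes of committed oligodendrocyte precursors 0 passed (0 adjusted over the list alone), with a median of 0.10, and of 25 cholesterol synthesis genes 0 passed (0 adjusted over the list alone), with a median of 0.02. Camera adjusted p-values of these 3 lists were 0.384, 0.183 and 0.707. Of 29 genes of myelin and mature oligodendrocytes 3 rose, 1 fell and 25 did not pass (4 rose and 1 fell adjusted over the list alone). Trf, encoding the iron carrier transferrin, went from 38.5 ± 3.60 to 82.0 ± 7.64 CPM (log2 fold change 1.09, SE 0.07, edgeR adjusted p = 0.000420), and it is also an abundant liver transcript. Apod rose by 1.06 (SE 0.16), the carbonic anhydrase gene Car2 by 0.46 (SE 0.08), and Cntn2, an adhesion molecule shared with neurons, was at -0.38 (SE 0.07). None of the 4 encodes a structural protein of compact myelin. Apod and Cntn2 lost the call without the pair numbered 3 (edgeR adjusted p 0.162 and 0.0695), and Car2 without the pair numbered 1 (0.0656) or 2 (0.0558). The list was higher as a set (camera adjusted p = 0.0159), with adjusted p = 0.416 with an estimated correlation, but without the pair numbered 1 its median was -0.07 and the set did not pass (camera adjusted p = 0.857). Nor did it pass with no filter on low counts (camera adjusted p = 0.054).

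**Figure D3:**
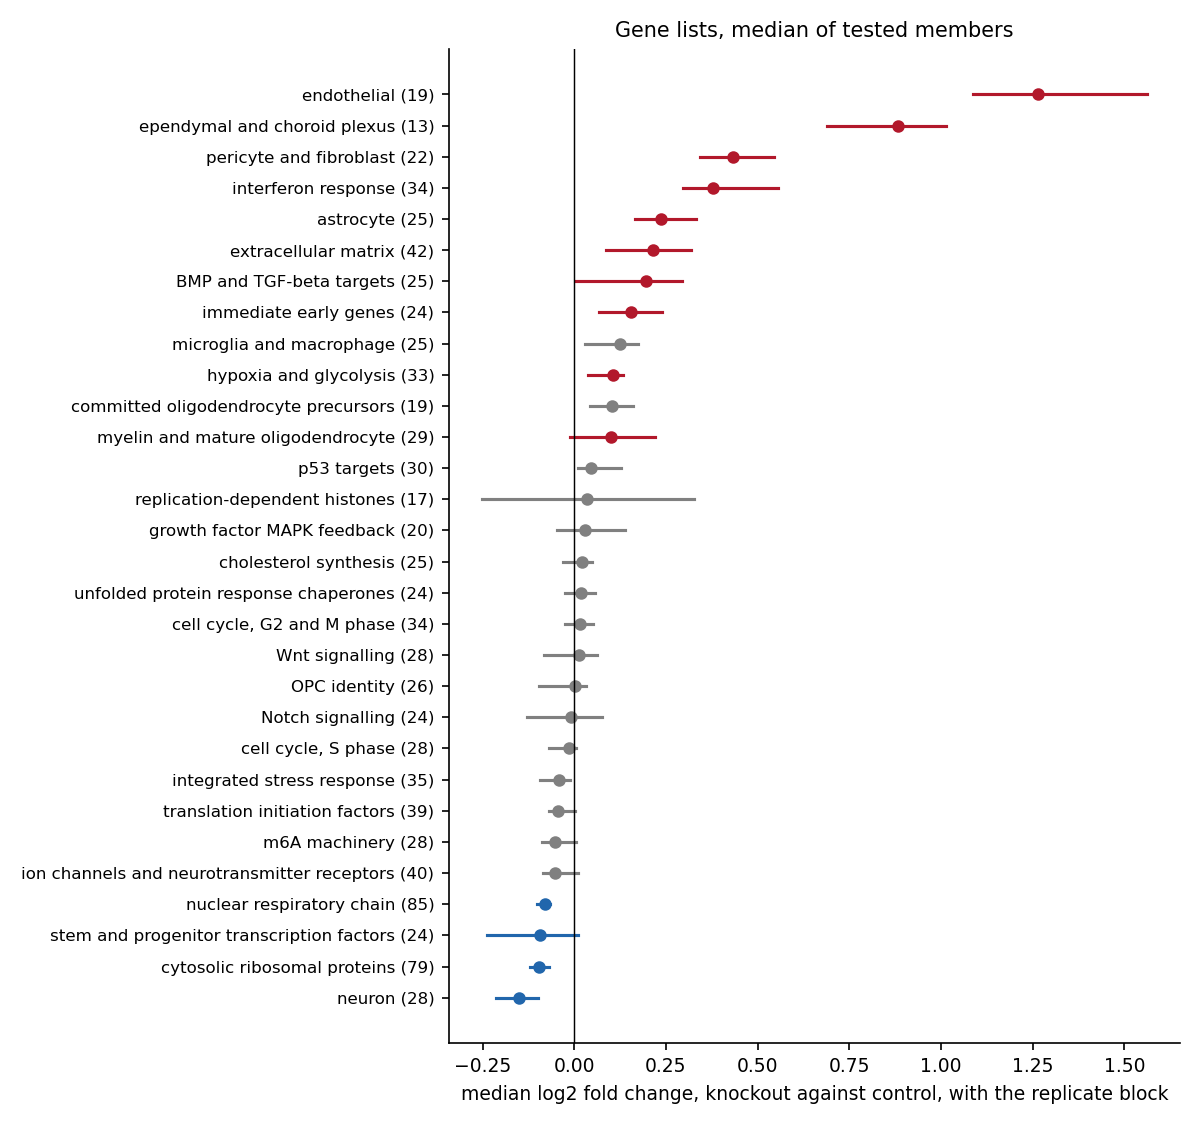
Median log2 fold change (horizontal axis, knockout against control with the replicate block) of the tested members of each of 30 gene lists, with the number of members in brackets and the 95% bootstrap interval over members as a line. Lists with a camera adjusted p under 0.05 are red where higher and blue where lower, from 1.26 for endothelial to -0.15 for neuronal markers, and the others are grey.

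Some genes of the extracellular matrix and some immediate early genes rose with the block, and some ribosomal protein and a few respiratory chain genes fell, while most members of each list did not pass. Over all 15906 tested genes 250 rose and 354 fell. Of 42 matrix genes 10 rose and 32 did not pass (16 rose adjusted over the list alone), with fibronectin (Fn1) from 85.3 ± 45.4 to 163 ± 113 CPM (log2 fold change 0.86, SE 0.09, edgeR adjusted p = 0.00258), Sparcl1 at 0.40 (SE 0.05) and Sparc at 0.38 (SE 0.05). The camera adjusted p was 6.8e-11, and adjusted p = 0.356 with an estimated correlation. The endothelial and pericyte markers above, which rose in the same libraries, share products of the vessel wall with this list. Of 24 immediate early genes 7 rose, 1 fell and 16 did not pass (9 rose and 1 fell adjusted over the list alone). Fos rose by 0.35 (SE 0.04) and Klf6 by 0.24 (SE 0.04), and Jund, a subunit of the AP-1 transcription factor, went from 481 ± 131 to 335 ± 81.8 CPM (-0.52, SE 0.04, edgeR adjusted p = 0.000574). The camera adjusted p was 0.00023, and adjusted p = 0.269 with an estimated correlation. That correlation was -0.026, below the preset 0.01, so correlation among these genes does not account for the lost call. Without the block this list did not pass (camera adjusted p = 0.0572). Klf6 lost the call without the pair numbered 1 or 3 (edgeR adjusted p 0.0565 and 0.0849). Of 79 cytosolic ribosomal protein genes 13 fell, 0 rose and 66 did not pass (26 fell adjusted over the list alone), among them Rpl13 (-0.30, SE 0.04), Rps28 (-0.39, SE 0.06) and Rpl36 (-0.42, SE 0.06). Processed pseudogenes of these genes can take up their reads, so single values are uncertain. Of 85 nuclear respiratory chain genes 4 fell, 0 rose and 81 did not pass (8 fell adjusted over the list alone), among them Atp5d (-0.31, SE 0.06) and Cox5b (-0.33, SE 0.06). Atp5d lost the call after GC correction (edgeR adjusted p = 0.0730, log2 fold change -0.23, SE 0.06, smaller by more than its SE) and without the pair numbered 1 or 2 (0.0610 and 0.0860), and Cox5b without the pair numbered 2 or 3 (0.0703 and 0.125). Camera adjusted p-values were 6.31e-12 and 6.02e-05 for these 2 lists, and adjusted p = 0.570 and adjusted p = 0.269 with an estimated correlation.

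Of 34 tested interferon-responsive genes 2 rose and 32 did not pass (9 rose adjusted over the list alone), with a median log2 fold change of 0.38 and 33 values above 0. The camera adjusted p of the list was 1.72e-09, and adjusted p = 0.269 with an estimated correlation and 0.111 with directional fry. B2m, the light chain of MHC class I, rose by 0.40 (SE 0.09, edgeR adjusted p = 0.0387) and Irf7, a regulator of interferon genes, by 0.75 (SE 0.18, edgeR adjusted p = 0.0494), and both lost the call after GC correction (0.0583 and 0.0592) at 0.38 (SE 0.09) and 0.77 (SE 0.17). For Irf7 the unadjusted p fell, and its call ended only because fewer genes were called, 371 against 604, which raises adjusted p-values. B2m also lost it without the pair numbered 1 or 3 (edgeR adjusted p 0.0956 and 0.154), and Irf7 without the pair numbered 2 or 3 (0.188 and 0.189) and under 4 other settings (highest 0.0680, with DESeq2). Of 25 BMP and TGF-beta targets 3 rose, 1 fell and 21 did not pass (3 and 1 adjusted over the list alone). Among them the basement membrane collagens Col4a2 and Col4a1, also on the matrix list and counted there, rose by 0.55 (SE 0.08) and 0.46 (SE 0.09). Id4 was at -0.24 (SE 0.05). The camera adjusted p was 0.00816, and adjusted p = 0.541 with an estimated correlation, and without the block the list did not pass (camera adjusted p = 0.287). Of 33 hypoxia and glycolysis genes 0 rose and 1 fell, Ddit4 at -0.22 (SE 0.04, edgeR adjusted p = 0.0264), and 32 did not pass (1 rose and 1 fell adjusted over the list alone). Their median was 0.10, with a camera adjusted p of 0.0159, and adjusted p = 0.559 with an estimated correlation. Without the pair numbered 3 the BMP and hypoxia lists did not pass (camera adjusted p 0.0998 and 0.154), and Col4a1 and Id4 lost the call (edgeR adjusted p 0.108 and 0.101). Id4 and Ddit4 lost it without any 1 of the pairs (lowest edgeR adjusted p 0.0804 and 0.0703), and Ddit4 also after GC correction (0.0555, at -0.20, SE 0.05, smaller by less than its SE). With all pairs kept, Col4a1 lost the call with DESeq2 (adjusted p = 0.132), and Id4 with library totals, upper quartile scaling and a mean of at least 5 CPM (edgeR adjusted p 0.0574, 0.0523 and 0.0685).

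Of the 30 lists tested, camera called 12 without the block (8 higher and 4 lower) and 14 with it (10 higher and 4 lower), and 0 with an estimated correlation. As that setting has few degrees of freedom, its 0 calls cannot decide whether the lists changed. The remaining lists did not pass as sets with camera with or without the block. Fry's test for change in either direction called 6 of these 16 with the block, namely Notch (adjusted p = 0.0263), MAPK feedback (0.0263), m6A (0.0275), Wnt (0.0355), integrated stress response (0.0355) and p53 (0.0461), and its directional test 0. Of 24 Notch signalling genes 4 fell and 20 did not pass (4 rose and 4 fell adjusted over the list alone), namely the ligands Dll3 (-0.58, SE 0.12) and Dll1 (-0.25, SE 0.06), Numbl (-0.25, SE 0.06) and Dtx1 (-0.26, SE 0.06), with edgeR adjusted p-values from 0.0305 to 0.0491. All 4 lost the call after GC correction (edgeR adjusted p 0.0984, 0.0734, 0.0516 and 0.407 in the same order), where Dtx1 shrank to -0.12 (SE 0.06) and Dll3 to -0.44 (SE 0.12) while Dll1 (-0.23, SE 0.06) and Numbl (-0.26, SE 0.06) moved by less than their SE and the unadjusted p of Numbl fell, and without the pair numbered 2 or 3 (0.0517 for Dll3 without the pair numbered 3 the lowest), and Numbl and Dll1 also without the pair numbered 1 (0.190 and 0.127). Single calls in other lists were Mcm2, a replication licensing gene, at -0.27 (SE 0.05), in 28 S phase genes, the cell cycle inhibitor Cdkn1a at 0.39 (SE 0.09) in 30 p53 targets, and Rbm15b, of the m6A methyltransferase complex, at -0.21 (SE 0.04) in 28 genes of the m6A machinery. Slc7a11, the cystine transporter, rose by 0.38 (SE 0.06) and Ddit4 was at -0.22 in 35 integrated stress response genes. Epha2 rose by 0.78 (SE 0.09) and Dusp4 was at -0.25 (SE 0.05) in 20 growth factor MAPK feedback genes, and the glutamate receptor subunit gene Grik5 was at -0.17 (SE 0.04) in 40 ion channels and receptors. Their edgeR adjusted p-values were 0.00375 for Epha2 and 0.0481 for Cdkn1a, with the others between, and Cdkn1a, Rbm15b and Grik5 lost the call after GC correction (0.0657, 0.0611 and 0.724), where Grik5 shrank to -0.03 (SE 0.04) while Cdkn1a (0.39, SE 0.09) and Rbm15b (-0.19, SE 0.04) moved by less than their SE. Epha2 was called without each of the pairs in turn. Mcm2 and Rbm15b lost the call without any 1 of them (lowest edgeR adjusted p 0.0849 and 0.0774), Dusp4 without the pair numbered 1 or 3 (0.0724 and 0.0769), Grik5 likewise (0.111 and 0.221), and Cdkn1a and Slc7a11 without the pair numbered 3 (0.143 and 0.0512). With library totals Numbl, Dll1, Dtx1, Rbm15b, Mcm2 and Grik5 also lost the call (edgeR adjusted p from 0.0514 for Mcm2 to 0.0765 for Grik5), all of these but Mcm2 with upper quartile scaling, and all but Rbm15b with a mean of at least 5 CPM. Cdkn1a lost it with DESeq2 size factors (0.0503) and with a mean of at least 5 CPM (0.0633). Adjusted over the list alone, 1 fell in the S phase, m6A and ion channel lists, 0 passed among p53 targets, 2 rose and 5 fell in the integrated stress response, and 3 rose and 2 fell in MAPK feedback. Of 34 genes of G2 and M phase, 24 chaperones of the unfolded protein response, 39 translation initiation factors, 28 Wnt signalling genes, 25 microglia and macrophage markers and 17 replication-dependent histone genes, 0 passed over all genes tested. Adjusted over the list alone 1 histone gene fell and 0 passed in the other 5 lists. Camera adjusted p-values of all these lists with the block lay between 0.0801 for the m6A machinery and 0.988 for G2 and M phase. The median, mean and camera direction differed in sign for the OPC identity, Notch, Wnt, G2 and M phase and histone lists.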

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

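The tests of liver transcripts, of the share of OPCs and of vascular cells were chosen only after the results were seen, and the liver list was written after them too. The share of read pairs in no gene was 20.8% ± 0.50 in knockout against 19.7% ± 0.665 in control libraries (SD, n = 3), outside the gene counts used for the comparison. The share of pairs of low alignment quality was 3.83% ± 0.248 against 3.11% ± 0.193, and that of unaligned pairs 1.25% ± 0.122 against 1.03% ± 0.0964. In each case all knockout libraries lay above all control libraries, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. The replicate block does not remove a difference of this kind. Whether it accounts for blocked calls such as Malat1 was not tested.

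Of 60 tested genes of the liver list, 9 rose and 6 fell with the block and the others did not pass, and the sum of all was 277 ± 33.3 CPM in control and 385 ± 33.3 CPM in knockout libraries (SD, n = 3). Alb, the most abundant, stood at 68.7 ± 8.98 and 133 ± 13.2 CPM, and 0 of these genes are on another fixed list. Expression by the cultured cells that varied with the replicate number is argued against by the mean correlation of same-numbered libraries over these genes, 0.226 (95% bootstrap interval -0.17 to 0.47). Expression-matched genes gave 0.541 or more in 1000 draws. Even expression across the cultures would also give a low correlation, so the test cannot decide on it. The coefficient of variation within groups was 11.5% for Alb, against a median of 71.8% for endothelial markers. A division of reads among copies is argued against by the summed Saa genes, which differed by -3.63 on the log2 scale. Such a division remains possible for the Serpina1 genes, whose sum differed by 0.070, and RNA or reads from outside the cultures, of a different make-up in each group, may account for the rest.

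With the block 12 of 19 endothelial and 6 of 13 ependymal and choroid plexus markers rose (adjusted p = 0.269 with an estimated correlation for both lists), and 7 of 28 neuronal markers fell (adjusted p = 0.381 with an estimated correlation). A lower share of OPCs alone, with the other cell types kept in proportion, would raise all of these. That is argued against by the neuronal median of -0.15 (95% bootstrap interval over genes -0.21 to -0.10) beside the endothelial rise. Neuronal means in the pairs were -0.368, -0.0154 and -0.144 against 1.00, 0.962 and 1.63 for endothelial markers, though the neuronal fall was near 0 in the pair numbered 2. OPC identity genes had a median of 0.00 (-0.10 to 0.03), with means in the pairs of 0.141, -0.146 and -0.138. These values cannot decide on a lower share of OPCs together with fewer neurons. A bias by GC content as the whole cause is argued against by medians after correction of 1.26 (1.11 to 1.55) for endothelial and -0.17 (-0.21 to -0.10) for neuronal markers. More vascular cells in the knockout preparations, which panning should mostly remove, stay open: 89.5% of endothelial markers were higher in the knockout library of all 3 pairs, but this restates the rise and decides nothing. An effect of Prrc2b loss on these transcripts apart from cell numbers was not tested.

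Genes that fell with the block had a median GC content of 57.5%, against 50.1% for those that rose and 49.8% for all tested genes. The correlation across genes of GC content with the blocked log2 fold change was Spearman -0.15, and also -0.15 without 228 neuronal and correlated genes (genes are not independent replicates). The trend thus did not rest on these genes. So small a part of 15784 genes could hardly have moved the correlation far, so the test cannot decide whether a lower level of neuronal transcripts was a cause. After GC correction 171 of 354 falls were still called, so a bias by GC content and a change in GC-rich genes cannot be told apart. The trend had the same sign in all 3 pairs (-0.151, -0.106 and -0.0824), but between 2 libraries of one group the correlation with GC content had a size of 0.0383 to 0.112, so trends as large as in the pairs numbered 2 and 3 also arose within a group.

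Splits of the 6 libraries into 3 and 3 number 10, and 4 part all pairs, too few for a share under 0.05. Without the block all 10 splits gave 0 genes and 0 genes changed at least 2-fold, the real split included. With the block the real split gave 604 genes and 81 changed at least 2-fold, against at most 0 and 0 in the other splits, so 1 of 4 was as large. For gene lists, 7 of 10 splits gave at least the 12 of the real split without the block, the highest 22. The 6 splits that keep 2 same-numbered pairs together gave 13 to 22 lists, which points to a structure of the samples by replicate number. With the block the real split gave 14 lists and the highest other 13, so 1 of 4 was as large.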

How the results depend on the processing

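The alternatives with the replicate block and the correction for GC content were chosen only after results were seen, except for the block itself. Without the block the edgeR count of called genes was 0 under all scalings, filters, limma-voom, GC correction and each left-out library, while DESeq2 called 20 (10 rising, 10 falling, 14 at least 2-fold). The replicate block, the paired alternative, called 604 genes (250 rising, 354 falling, 81 at least 2-fold), with Prrc2b at -0.41, and added the immediate early and BMP lists. It changed no other list call, and of the genes always named it changed the calls of Prrc2b and Sox2 only. Lists higher in the knockout numbered 8, but 4 with no filter and 5 with limma-voom. With an estimated correlation, and with fry in place of camera, 0 lists were called, 0 up and 0 down, with or without the block. DESeq2 gave no list result.

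With each library left out and no block, lists called ranged from 10 to 19, up 5 to 13 and down 4 to 10. Log2 fold changes that reversed ranged from -1.17 to 0.093 for Olig2, -0.043 to 2.33 for Ttr, -1.79 to 0.47 for Neurod2, -0.59 to 0.12 for Dlx1, -0.92 to 1.76 for Vtn, -1.29 to 2.26 for Rgs5, -0.076 to 0.79 for Sparc, -0.56 to 1.63 for Col4a2, -0.50 to 1.35 for Col4a1, -0.079 to 2.18 for Apod, -1.57 to 0.87 for Cntn2, -0.024 to 0.40 for Ptprz1, -0.18 to 0.33 for Pdgfra and -0.026 to 0.034 for Prrc2c. List medians ranged from -0.13 to 0.50 for matrix, -0.011 to 0.48 for astrocyte, -0.30 to 0.030 for neuronal, -0.77 to 1.63 for pericyte and fibroblast, -0.015 to 0.30 for immediate early and -0.13 to 0.34 for BMP genes, and those of 3 further lists crossed 0, from -0.26 to 0.042 for progenitor factors, -0.062 to 0.26 for myelin and -0.045 to 0.20 for hypoxia genes. These fits hold unequal numbers of each replicate number. With GC correction Prrc2c was at -0.0084, and at -0.0089 with the block.

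With the block, 231 genes fell with library totals, and no filter gave 1034 calls (478 rising, 556 falling). A mean of at least 5 CPM left 43 genes changed at least 2-fold, as fewer genes were tested, limma-voom called 7 lists down, and GC correction gave 371 calls, 175 falling. Adjusted p under 0.01 and 0.1 gave 97 and 1102 genes, and glmTreat against a fold of 1.5 gave 11. Leaving out a pair gave 174 to 521 genes, 62 to 276 rising, 112 to 270 falling and 33 to 131 at least 2-fold, lists down 4 to 8, medians of the myelin list from -0.071 to 0.27 and Prrc2c from -0.023 to 0.040. Of 79 named calls, 36, 16 and 15 were lost without the pairs numbered 3, 1 and 2, where 1 residual degree of freedom was left, and 12 with GC correction. None of the 79 changed sign in these settings. The 604 calls had the same sign under each alternative with the block in which they were measured. Except where fewer genes or libraries were used, the cause was not tested. In the simulated data without the block, where libraries shared no replicate differences, changes under 2-fold were rarely detected. In the real data larger differences were not called either, such as Saa1 at -3.25 and Malat1 at 1.71 on the log2 scale (edgeR adjusted p = 0.113 for both without the block). Whether these are effects of the knockout was not tested.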

Other observations

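No tests were added here, and the values were looked up after the results were seen, under a check of sex-linked genes named beforehand. Xist, the non-coding RNA of the inactive X chromosome, stood at 937, 2.33 and 2791 CPM in the control libraries numbered 1, 2 and 3, and at 2720, 2559 and 2.53 CPM in the knockout libraries. The Y-linked Ddx3y stood at 112, 181 and 0.177 CPM in control and at 0.0364, 35.2 and 164 CPM in knockout libraries. Control library 1 and knockout library 2 held both transcripts at over 30 CPM. Within each group the libraries differed in this pattern, so they were not the same pool of cells divided. Same-numbered libraries did not share the pattern of these genes. Of the genes called with the block, 14 lie on the X and 0 on the Y chromosome.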
